A study of Homo sapiens with 10 samples.

How the data were processed

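CUT&RUN libraries of gamma-H2AX, H2AX and H3K27me3 from K562 and HepG2 cells were analysed from the deposited signal tracks and peak lists. Reads had been aligned to hg19; BWA 0.7.12, SAMtools and MACS2 are named per the submitters' processing notes, which as used here give neither their roles nor their settings. The deposited signal tracks hold read coverage as the mean depth per base in 1-kb bins. The bins, the same in all libraries, and the gaps between them were used as read. Every value is a whole number of thousandths, within a tolerance of 0.02 thousandths, and the means differ between libraries, so the deposited coverage was not scaled to depth. Of the bins with a value above 0 and below 250 thousandths, 61.5% to 63.7% fell on multiples of 60 bp in the K562 1 h gamma-H2AX and H3K27me3 libraries, against 0.778% to 1.04% on multiples of 41 bp. In the other 7 libraries 59.0% to 65.3% fell on multiples of 41 bp, against 0.732% to 0.849% on multiples of 60 bp. These steps were taken as the read length. On that reading the tracks hold, in units of 1e6 reads, 67.2 and 83.1 for K562 gamma-H2AX at 1 h, 22.3 and 40.4 at 24 h, 35.7 for HepG2 gamma-H2AX, 45.9 and 45.8 for K562 H2AX, 42.7 and 43.8 for HepG2 H2AX and 51.1 for H3K27me3. Between replicates, the variance over windows exceeded sampling noise by 56.3-fold at 1 h, 191-fold at 24 h, 4.83-fold in K562 H2AX and 3.15-fold in HepG2 H2AX, so no pair differed by as little as sampling of the same library would give. This takes reads as independent molecules, and at the lower ratios sampling remains a sizeable part of the spread.

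The deposited peak lists give, for each peak, a fold enrichment, an integer score and −log10 of the p-value and q-value, in the layout of MACS2; the control used for the fold is not given in the sources used here. Per the labels there is a list for each gamma-H2AX library, called per library. The K562 1 h lists have the layout of broad peaks and the others that of narrow peaks. The deposited score column was about the −log10 q column scaled and was not used.

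Bins were averaged into 100-kb windows, keeping windows with at least 50% of their bins and leaving out chromosome Y, and each value was divided by the mean of its library. Windows in which the H2AX libraries of both lines averaged at least 0.25 of their library means were tested on log2(relative depth + 0.05), so fold changes understate the change of windows near 0. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, all 10 libraries in a single fit with 6 group means, 4 residual degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05. Group means with a single library (HepG2 gamma-H2AX and H3K27me3) use the spread of the 4 groups that have 2. The labels do not say that replicates are separate cultures, so p-values measure the spread between these libraries, which may be technical. On simulated data with 200 changed windows out of 27764, the comparison of K562 1 h with H2AX recovered 0 at a log2 change of 0.5 and 77.5% at a log2 change of 1, with 8 false calls. The comparison of HepG2 with H2AX recovered 63.5% at a log2 change of 1, with 4 false calls. The simulated spread came from the K562 1 h, K562 H2AX and HepG2 H2AX replicates, and the 24 h pair was left out. The recovered shares therefore do not describe the fit to the real data, whose shared spread includes that pair.

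Groups, tests, the windows to be named and the alternatives were fixed before the data were examined, apart from settings described as outside the plan or chosen afterwards. The windows named are the 10 highest and 10 lowest by log2 fold change with adjusted p under 0.05 and the same direction in every pair of libraries, or the 3 lowest p in each direction where none passed; for peaks, the 5 highest folds of long lists and up to 10 peaks of short ones. The plan allowed for counts or for other values; as the tracks hold depth, the branch for values that are not counts was used, and the count models, count scalings and count filters were not run. Median-of-ratios scaling was used as the other scaling. Relative to library-mean scaling it raised the levels of H3K27me3 by 1.23 on the log2 scale, and it moved those of 24 h replicate 1 by -0.37 and those of the other libraries by -0.17 to -0.03.

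Peak lists were compared by overlap of at least 1 bp, with 1000 shuffles of positions within chromosomes. Bins touched by peaks of both K562 1 h lists gave the share of signal in peaks, and the local fold set these bins against the other bins of the same windows. H3K27me3 and gamma-H2AX were related over 10-kb windows, each divided by a different H2AX replicate so that no control library was shared. The plan named a correlation of the 2 marks across 100-kb windows, and neither 10-kb windows nor division by H2AX. The K562 H2AX replicates had a Spearman's rho of 0.899 over these windows, so their common pattern still enters both ratios. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Gene bodies, promoters and the gene lists planned for them were not analysed here, because an annotation of hg19 was not used here. Alternatives covered the pseudocount, the filter, the scaling, the window size, the libraries in the fit, the replicate number as a block, each replicate left out, stricter peaks and overlap, and the removal of the 0.1% of bins with the highest H2AX signal. Because 24 h replicate 1 reads 0 wherever the 1 h tracks are high, each test was also run without it. In the comparisons that use the 24 h group, leaving it out was fixed before the data were examined. In the other comparisons, or together with a further change, leaving it out was chosen after seeing the data.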

Results

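Gamma-H2AX, the form of the histone variant H2AX that is phosphorylated around DNA double-strand breaks, was profiled by CUT&RUN, in which an antibody-tethered nuclease releases the DNA under its target for sequencing. K562 is a human erythroleukaemia line that carries the Philadelphia translocation between chromosomes 9 and 22, and HepG2 is a human liver carcinoma line. Irradiated cells received 6 Gy from a cobalt source and recovered for 1 h or 24 h. The libraries comprised gamma-H2AX in K562 at 1 h (n = 2) and 24 h (n = 2), gamma-H2AX in HepG2 at 1 h (n = 1), H2AX in untreated K562 (n = 2) and untreated HepG2 (n = 2), and the Polycomb-associated repressive mark H3K27me3 in K562 at 1 h (n = 1). The antibody label of the H2AX libraries names histone H4, so these serve here as the untreated chromatin background whichever histone was bound. Mean depth per base over bins of 1 kb was 1.43 and 1.77 in the K562 1 h replicates and 1.09 in the H3K27me3 library. It was 0.324 and 0.588 in the K562 24 h replicates, 0.518 in HepG2 gamma-H2AX, 0.667 and 0.666 in K562 H2AX, and 0.620 and 0.637 in HepG2 H2AX. Levels below are relative to the mean of the same library, positions are in hg19, and windows span 100 kb unless stated. Genes were not assigned to windows, because an hg19 annotation was not used here.

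The comparison of K562 gamma-H2AX at 1 h with untreated H2AX asked where in the genome the mark lay after irradiation. Gamma-H2AX was uneven over the chromosomes: its log2 ratio to H2AX ran from -1.35 at the 5th percentile of windows to 0.79 at the 95th, whereas the log2 ratio of the 1 h replicates to each other ran from -0.33 to 0.62 and that of the H2AX replicates from -0.20 to 0.15. Among windows that passed the test given below, the deepest deficits lay on chromosomes 19 and 20. On chromosome 19 the window at 7200001 to 7300000 had a log2 fold change of -2.29 (SE 0.32, limma adjusted p = 0.0432, n = 2 against 2), its neighbour from 7100001 had -2.25, and windows starting at 9100001, 15000001, 13400001, 16800001 and 13600001 had -2.05, -2.01, -2.00, -1.96 and -1.96. On chromosome 20 the windows from 1800001 to 2000000 both had -2.00, and on chromosome 10 the window from 47300001 had -1.91. H3K27me3 in the 9 windows on chromosomes 19 and 20 lay between 2.72 and 4.58 times its library mean, and in the window on chromosome 10 it was 0.706 times that mean.

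Windows above H2AX at 1 h included 3 neighbours on chromosome 13 between 67400001 and 67700000, with log2 fold changes of 0.99, 1.09 and 1.22, and a pair on chromosome 9 between 27300001 and 27500000, with 1.01 and 1.18. On chromosome X the windows from 44900001, 153600001 and 137900001 rose by 1.12, 1.07 and 1.04. The windows from 61200001 on chromosome 20 and 39900001 on chromosome 17 rose by 1.05 and 0.98, the latter with a limma adjusted p = 0.0492. Under median-of-ratios scaling 1 of these 10 windows lost its call. At 67600001 on chromosome 13 the relative levels were 1.16 and 1.13 in the gamma-H2AX replicates and 0.419 and 0.508 in H2AX. H3K27me3 was below 0.5 of its mean in all 10 of these windows except the one on chromosome 20, where it was 1.27. Its median depth over 1-kb bins was 0.238 against a mean of 1.09, so most bins lie below 0.5 of the mean and such levels do not single out these windows. The 10 windows are the largest rises among those that passed the test, not the largest rises. On chromosome 17 the window from 27400001 had 3.06 and 4.71 at 1 h against 1.03 and 0.877 in H2AX, and is not among them. There 24 h replicate 1 read 0.0189, which widens the shared spread, so the list favours windows where that track holds signal.

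In the test across all libraries, 5107 of 27764 windows differed between K562 gamma-H2AX at 1 h and H2AX, 143 higher and 4964 lower, and every one of them had the same direction in all pairs of libraries. Direction was also the same in all pairs for 88.6% of all windows tested, called or not. The shared spread included replicate 1 of the 24 h group, whose track read 0 over much of the genome; without it 19666 windows passed, 9228 higher and 10438 lower, and these held all 5107. With that library in the fit, leaving out either 1 h replicate or either H2AX replicate gave 0 calls. Most thinly covered bins fell on steps of 60 bp in the 1 h libraries and of 41 bp in the H2AX libraries, which was taken as the read length, so read length and group coincide in this comparison. The H3K27me3 library, also with 60-bp steps, deviated from H2AX in the opposite direction to gamma-H2AX at 1 h (Spearman's rho -0.771 over windows, negative in each of 23 chromosomes). H3K27me3 has a pattern of its own, so this does not separate read length from group.

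**Figure D1:**
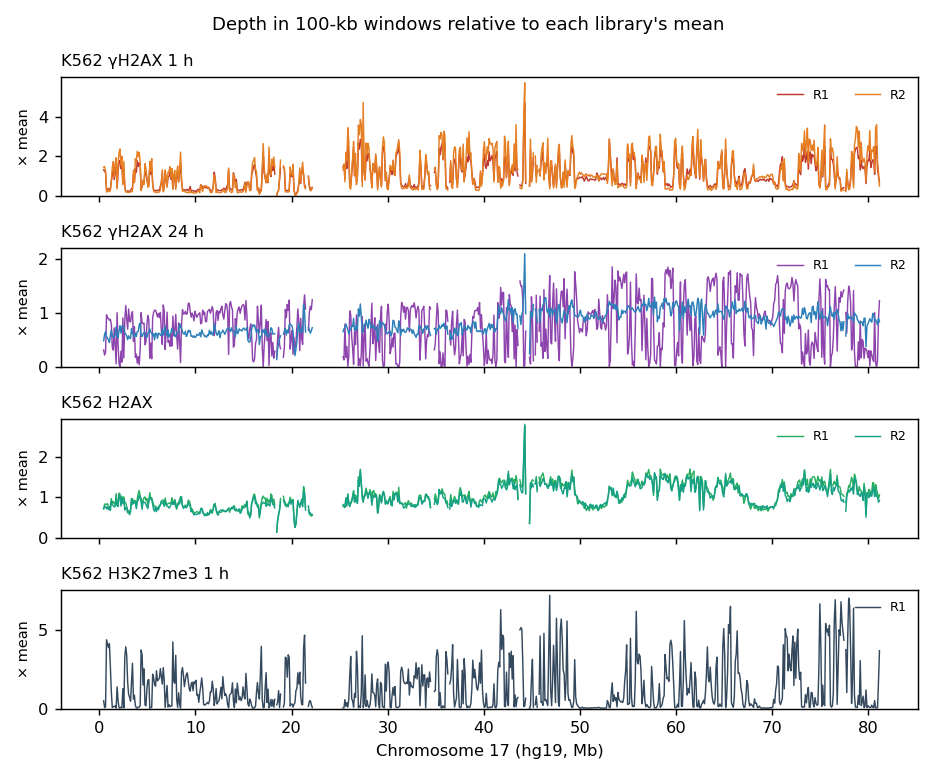
Depth in 100-kb windows along chromosome 17 (x axis, hg19, Mb) as a multiple of the mean of each library (y axis), with a line per replicate; gaps hold no retained bins. The K562 gamma-H2AX 1 h replicates rise and fall together, 24 h replicate 1 drops to 0 where they are high, and H3K27me3 is high where they are low.

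The deposited peak lists described the same libraries at finer scale. K562 at 1 h had 41947 peaks over 52.3 Mb in replicate 1 and 46072 peaks over 78.8 Mb in replicate 2. Of the replicate 1 peaks, 59.5% overlapped a replicate 2 peak, against 5.43% for shuffled positions (permutation p = 0.001, adjusted p = 0.0015 over 6 overlaps tested), and 49.3% of replicate 2 peaks overlapped replicate 1, against 4.70% shuffled (p = 0.001 by the same permutation test). That p is the smallest that 1000 shuffles can give. The shuffles placed peaks over all bins of a chromosome, so they do not account for peaks lying where coverage is high in other libraries too. Bins touched by peaks of both lists had 1.86 and 1.75 times the library mean in the untreated K562 H2AX replicates. The peaks were shallow: the median fold given by the authors' peak caller was 1.78 and 1.76, and only 8.10% and 14.7% had q under 0.05. The highest folds of replicate 1 were 5.26 on chromosome 4 at 89772645 to 89773265, 4.94 and 4.80 on chromosome 15 from 41264835 and 41087845, 4.89 on chromosome 9 from 127162014 and 4.85 on chromosome 5 from 82406050. Those of replicate 2 were 4.96 on chromosome 7 at 32908961 to 32909366, 4.94 on chromosome 10 from 135218635, 4.89 on chromosome 2 from 191370407, 4.75 on chromosome 8 from 100896036 and 4.60 on chromosome 1 from 154230847.

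The 26075 regions shared by both 1 h peak lists touched 1.91% of bins and held 8.01% ± 0.649 (SD, n = 2) of the 1 h signal. Untreated K562 H2AX had 3.44% ± 0.156 (SD, n = 2) of its signal there, K562 24 h replicate 2 had 2.72%, HepG2 gamma-H2AX 1.94%, HepG2 H2AX 2.21% ± 0.0452 (SD, n = 2) and H3K27me3 0.240%. Against the other bins of the same windows, which share the copy number of the peaks, the level in peaks was 1.87-fold ± 0.00737 (SD, n = 2) at 1 h, 1.14-fold ± 0.0163 (SD, n = 2) in K562 H2AX, 1.09-fold in 24 h replicate 2 and 0.166-fold for H3K27me3. These peaks were called on the 1 h libraries, so the 1 h values are not independent of the choice of regions.

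The comparison of 1 h with 24 h asked how the distribution of gamma-H2AX changed during recovery. In K562, the log2 ratio to H2AX spread less over windows in 24 h replicate 2 (SD 0.28) than at 1 h (SD 0.69). The relative levels of 24 h replicate 2 correlated with those of the 1 h replicates with a Spearman's rho of 0.563 and 0.415, and with those of untreated H2AX with 0.774 and 0.838. With each time divided by a different H2AX replicate, the rho between 1 h and 24 h replicate 2 was 0.159, positive in 17 of 23 chromosomes. The windows that were higher at 1 h by the most were on chromosome 1 from 54700001 (log2 fold change 4.18, SE 1.36, limma adjusted p = 0.0472, n = 2 against 2), chromosome 17 from 27400001 (4.13), chromosome 11 from 72400001 (4.03), chromosome 6 from 17800001 (4.01), and chromosomes 12 and 10 from 124900001 and 72400001 (3.88 each). Next came chromosome 17 from 80800001 and 35500001 (3.86 and 3.85), chromosome 16 from 67900001 (3.83) and chromosome 11 from 68100001 (3.82). These sizes rest on the zeros of 24 h replicate 1: against 24 h replicate 2 alone the log2 fold changes in the first 4 were 1.83, 2.46, 1.93 and 1.72, and they were 1.72 to 1.93 in the other 6. The zeros lie where the 1 h tracks are high, so a difference from that library was fixed in advance in such windows. The p-values of these windows therefore do not test recovery, and only 24 h replicate 2 informs the 24 h side. With a smaller pseudocount 7 of the 10 lost their call, and without 1 h replicate 1 all 10 did.

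Of the 10 named windows lower at 1 h than at 24 h, 7 lay on chromosome 6, which as a whole was not low at 1 h (log2 ratio to H2AX 0.04). The window on chromosome 10 from 47300001 had -2.25 (SE 0.23, limma adjusted p = 0.0138, n = 2 against 2). On chromosome 6, windows starting at 138900001, 114000001, 107900001, 106000001, 105900001, 132900001 and 112500001 had log2 fold changes from -2.22 to -2.11. Chromosome 19 from 7100001 had -2.17 and chromosome 8 from 121000001 had -2.14. Against 24 h replicate 2 alone, the log2 fold changes of these 10 windows lay between -1.96 and -1.71. At 138900001 on chromosome 6 the relative levels were 0.612 and 0.344 at 1 h, 1.92 in 24 h replicate 2, 1.81 and 1.72 in H2AX and 4.06 for H3K27me3.

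In total 13028 windows differed between 1 h and 24 h, 3141 higher at 1 h and 9887 lower; without 24 h replicate 1 there were 15855, 5662 higher and 10193 lower, of which 12907 were shared. Fitting only the 4 libraries compared gave 0 calls, as did leaving out 1 h replicate 2. Leaving out 1 h replicate 1 gave 9490, of which 701 were higher at 1 h, and leaving out 24 h replicate 2 gave 22660. The 24 h libraries carried 41-bp steps, so recovery time and read length coincide here as well. Where 24 h replicate 1 reads 0 because the 1 h tracks are high, a call of higher at 1 h does not test recovery.

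Replicates of 3 groups resembled each other and those of the 24 h group did not. Over 27764 windows, Spearman's rho was 0.948 between the K562 1 h replicates, 0.980 between the K562 H2AX replicates and 0.913 between the HepG2 H2AX replicates, but 0.0536 between the 24 h replicates. In 24 h replicate 1, all 933070 bins (33.1%) in which the mean depth of the 1 h replicates exceeded 1.642, the highest at which the library held signal, read exactly 0, while 0.316% of the same bins read 0 in 24 h replicate 2. The track of 24 h replicate 1 was thus not independent of the 1 h tracks, and counts without it are given beside those of the group.

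**Figure D2:**
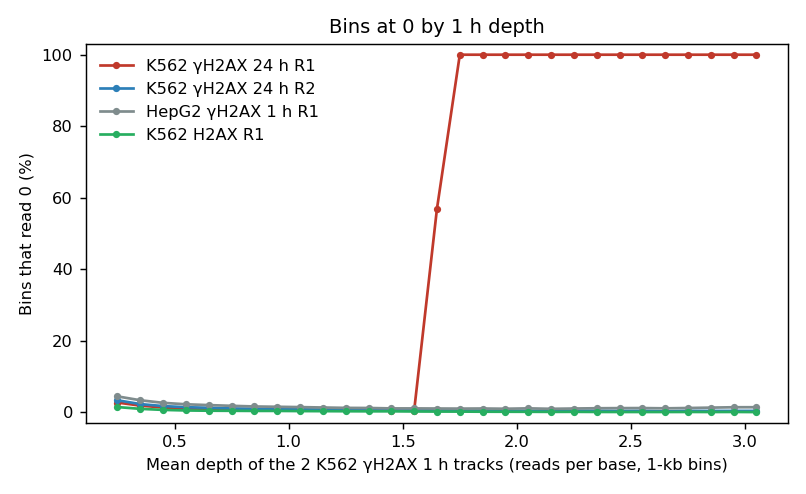
Percent of 1-kb bins that read 0 (y axis) against the mean depth of the K562 gamma-H2AX 1 h replicates in reads per base (x axis), for 4 libraries; each point is a depth class. In 24 h replicate 1 the share steps to 100% above 1.642, and in the other libraries drawn it stays low.

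**Figure D3:**
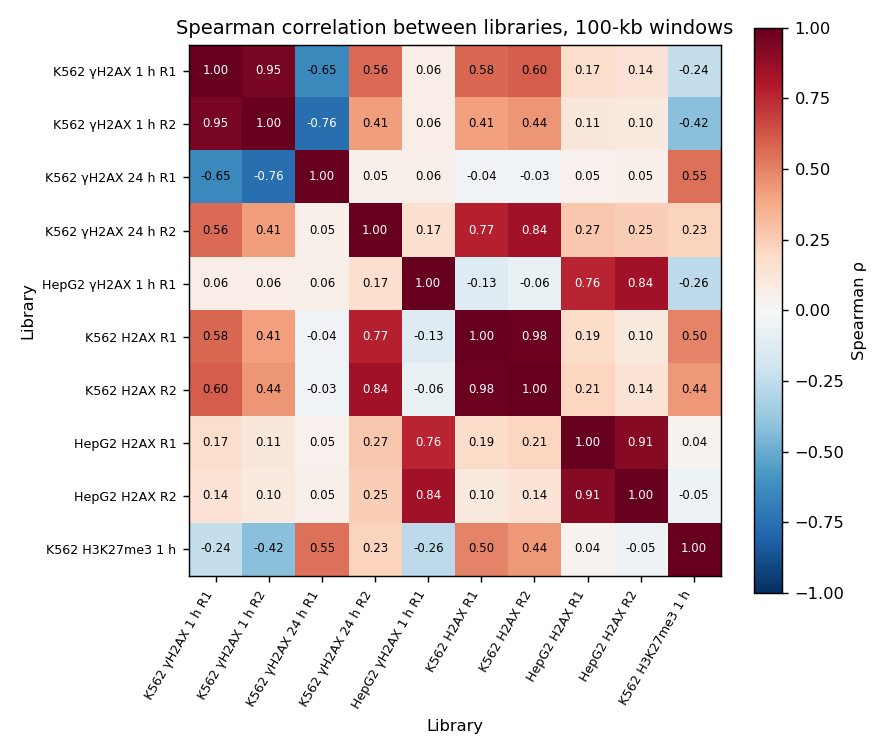
Spearman's rho between all pairs of the 10 libraries over 100-kb windows, printed in each cell and coloured from -1 to 1. The replicates of K562 at 1 h (0.948) and of both H2AX groups are close, whereas the 24 h replicates have 0.0536.

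The comparison of 24 h with untreated H2AX asked whether the distribution of gamma-H2AX after recovery departed from the untreated background. Levels are relative to the mean of each library and the background is another antibody, so the comparison cannot show how much of the mark remained. No window passed limma's test (0 of 27764 at adjusted p under 0.05, with 6151 at an unadjusted p under 0.05), and without replicate 1 the count was also 0 (8059 unadjusted). In replicate 2 the log2 ratio to H2AX spanned -0.44 to 0.45 between the 5th and 95th percentiles, compared with -1.35 to 0.79 at 1 h. The windows with the lowest p, none passing, were higher on chromosome 4 from 162400001, 163100001 and 162000001 (log2 fold changes 0.87, 0.94 and 0.79) and lower on chromosome 17 from 44700001, chromosome 2 from 241400001 and chromosome 22 from 28200001 (-0.64, -0.69 and -0.81; adjusted p = 0.224 for all 6). In replicate 2 alone these log2 values were 0.66, 0.71 and 0.60, and -0.46, -0.64 and -0.66. Without replicate 2, leaving the track that reads 0 as the whole group, 20709 windows passed.

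The 24 h peak lists were short, with 8 peaks in replicate 1 and 13 in replicate 2, and 0 peaks in common. All 21 overlapped shared 1 h peaks, against 2.24% and 2.92% for shuffled positions (permutation p = 0.001 for each list), and 19 of them lay in the 81 windows (0.292%) where untreated K562 H2AX was at least 3 times HepG2 H2AX. Those windows were on chromosomes 22 (43 windows), 13 (30) and 9 (8). The shuffles placed peaks over all bins of a chromosome, so the permutation test does not account for the concentration of peaks in such windows. It therefore does not show that 1 h sites persisted. In replicate 1 the highest folds given by the caller were 6.27 on chromosome 7 from 132671380, 5.88 on chromosome 12 from 58217045, and 5.08 and 5.03 on chromosome 22 from 17121906 and 17110901; the other 4, from 23539117 and 22157103 on chromosome 22 and 134017628 and 134042622 on chromosome 9, had 3.85, 3.85, 3.56 and 3.43. In replicate 2 they were 6.86 and 6.68 on chromosome 22 from 22647807 and 22645284, 4.84 on chromosome 9 from 133607359 and 4.78 on chromosome 22 from 20886589; the next 6 lay on chromosomes 22 and 9 with folds of 3.51 to 4.16. At the 13 replicate 2 peaks the median level was 5.91 times the library mean in 24 h replicate 2, 8.30 and 7.02 times in the untreated H2AX replicates, and 18.5 and 23.5 times at 1 h. The 24 h and HepG2 lists are narrow peaks and the 1 h lists broad peaks, so their numbers of peaks cannot be compared.

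In HepG2 at 1 h, gamma-H2AX followed untreated H2AX closely. The log2 ratio spanned -0.33 to 0.26 between the 5th and 95th percentiles, a width of 0.59 against 2.13 in K562 at 1 h, and its values have no replicate. No window passed limma's test, in which this library was assumed to vary like the others (0 of 27764, with 114 at an unadjusted p under 0.05, and 0 with 1725 unadjusted without K562 24 h replicate 1); fitting only the 3 HepG2 libraries gave 8557. The windows with the lowest p, none passing, were higher on chromosome 9 from 23800001, 24100001 and 24400001 (0.39, 0.35 and 0.34) and lower on chromosome 9 from 22200001 and 132200001 and chromosome 17 from 79700001 (-0.23, -0.61 and -0.80; adjusted p = 1.00 for all 6). The 4 windows on chromosome 9 between 22200001 and 24500000 lie in a segment where K562 reads about 0 in every library, which shrinks their shared spread. Of the 170 HepG2 peaks, 169 were centred outside the bins analysed here and 14 lay on chromosome Y. The highest folds given by the caller were 40.5, 39.9 and 36.5 on chromosome Y from 58855928, 58827146 and 58862668, 30.4 on chromosome 3 from 96336235 and 24.3 on chromosome 16 from 46432596. Of the 170, 0 overlapped a shared K562 1 h peak. All peaks of both K562 1 h lists were centred inside the bins analysed, so this overlap could hardly differ from 0 and does not compare the lines.

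Setting each line against its own H2AX, K562 and HepG2 differed at 1 h by log2 values from -1.28 to 0.93 between the 5th and 95th percentiles. The windows with the lowest p were relatively higher in K562 on chromosome 9 from 27400001 and chromosome 17 from 17700001 and 40200001 (log2 differences 1.21, 1.17 and 1.38), and relatively lower on chromosomes 16, 17 and 10 from 16500001, 20400001 and 47300001 (-1.63, -1.58 and -2.28). None passed in limma's test on all libraries (adjusted p = 0.331 for these 6; 0 windows in total, 4138 at an unadjusted p under 0.05). Without K562 24 h replicate 1, which belongs to neither side of the comparison and was left out after the count of 0 was seen, 12654 windows passed, 4521 relatively higher in K562 and 8133 lower, and fitting only the compared groups gave 13141. The HepG2 arm is 1 library with a borrowed spread, so the count rests on which libraries set that spread. HepG2 gamma-H2AX carried 41-bp steps, so cell line and read length coincide too.

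Relative to H2AX, gamma-H2AX at 1 h was low in K562 where H3K27me3 was high. Over 276048 windows of 10 kb, each mark divided by a different H2AX replicate, Spearman's rho was -0.763 for 1 h replicate 1 and -0.822 for replicate 2 (Pearson's r -0.767 and -0.845), and it was negative in each of 23 chromosomes for both. The median gamma-H2AX ratio in the lowest H3K27me3 decile was 2.88- and 4.52-fold that in the highest. In 24 h replicate 2 the same ratio was 1.02-fold with rho -0.0994, and HepG2 gamma-H2AX over the K562 deciles gave 1.12-fold with rho -0.161. The end deciles hide a rise and fall in 24 h replicate 2. Its median log2 ratio was -0.12 in decile 1, 0.15 in decile 4 and -0.15 in decile 10, so it declined with H3K27me3 from decile 4 on. Windows are not independent replicates. At 1 Mb the rho of 24 h replicate 2 was -0.623, close to the -0.599 and -0.660 at 1 h, so the contrast between the times holds for the finer scale. Without division by H2AX, the rho of the 1 h replicates was -0.385 and -0.583 at 10 kb, -0.238 and -0.422 at 100 kb, and 0.198 and 0.0213 at 1 Mb, so at 1 Mb the levels themselves were not inversely related. The plan named the setting at 100 kb without division, whose rho is much weaker than at 10 kb with division.

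**Figure D4:**
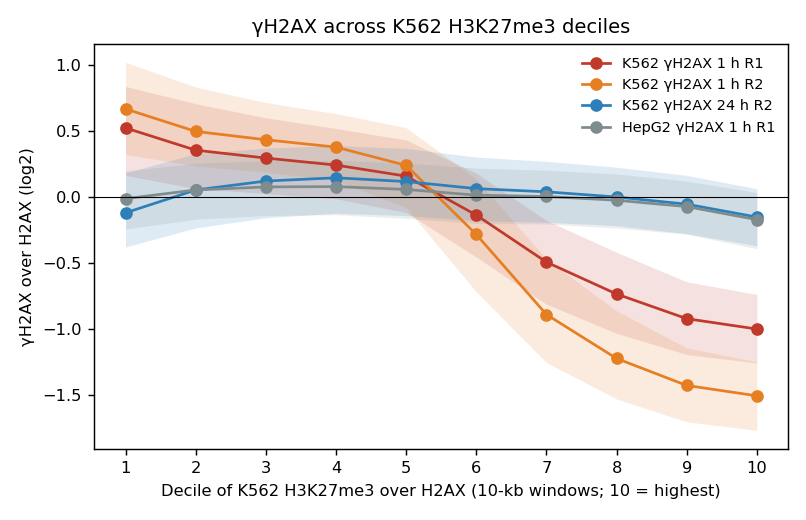
Median log2 ratio of gamma-H2AX to H2AX (y axis) in 10-kb windows grouped by decile of K562 H3K27me3 over H2AX (x axis), for 4 libraries; bands span the quartiles of windows. Both 1 h replicates fall across the deciles, replicate 2 from 0.67 to -1.51, and 24 h replicate 2 and HepG2 stay near 0.

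Tested window by window, H3K27me3 was most above gamma-H2AX on chromosome 17 from 77100001 (log2 fold change 4.36, SE 0.42, limma adjusted p = 0.000186, n = 1 against 2), chromosome 9 from 135300001 and 135000001 (4.16 and 4.10) and chromosome 1 from 10800001 and 10900001 (4.13 and 4.02). Chromosomes 13, 17, 11, 20 and 22 followed, from 113600001, 77900001, 1800001, 61600001 and 18900001, with 4.06, 4.06, 4.02, 4.02 and 4.02. It was most below gamma-H2AX on chromosome 5 from 43600001 (-4.98, SE 1.67, limma adjusted p = 0.0309, n = 1 against 2), chromosome 7 from 102400001 (-4.98), chromosome 12 from 51000001 (-4.97) and chromosome 3 from 47900001, 33600001 and 47000001 (-4.95, -4.94 and -4.94). In all, 23153 windows differed, 8391 with more H3K27me3 and 14762 with less; under median-of-ratios scaling, which raised H3K27me3 by 1.23 on the log2 scale, the split was 11815 and 10176. Of the 10 named lower windows, 9 lost their call under that scaling, 5 with a smaller pseudocount, and all 10 when either 1 h replicate was left out. With the replicate number as a block, 8 of them lost it. The lone H3K27me3 library was assumed to vary like the others, and all 3 libraries carry 60-bp steps. The shared spread of the named lower windows included 24 h replicate 1, a library on neither side of this comparison. At 43600001 on chromosome 5 it read 0.0088 of its mean, against 1.52 in 24 h replicate 2. Without it the log2 fold change there was still -4.98. The SE and the lost calls of the named lower windows therefore depend on that library as well as on the 2 marks.

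Whole chromosomes moved little. The mean log2 ratio of K562 gamma-H2AX at 1 h to H2AX was highest on chromosome 17 (0.15, from 0.04 to 0.25 over pairs of libraries) and 0.08 on chromosomes 4 and 3. It was lowest on chromosome 19 (-0.18, from -0.31 to -0.04) and chromosome 20 (-0.15, from -0.20 to -0.11). In HepG2 the lowest ratios were -0.27 on chromosome 22 and -0.17 on chromosome 17, without a replicate.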

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

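All tests of explanations in this part were chosen after the result was seen. The change of gamma-H2AX over H2AX at 1 h differed between K562 and HepG2 in 12654 windows by a test of the difference itself, once K562 24 h replicate 1 was left out of the shared spread. With it, as planned, the count was 0, and since the HepG2 spread is borrowed from other groups the count rests on which libraries set it. HepG2 gamma-H2AX stayed close to its H2AX, with a log2 span of 0.59 between the 5th and 95th percentiles against 2.13 in K562. Lower depth argues poorly for this, since sampling noise would widen a span and not narrow it. A library with little specific signal may account for it: the HepG2 profile over H2AX had a Spearman's rho of 0.723 with that of K562 24 h replicate 2, positive in all 23 chromosomes, and 0.161 with that of K562 at 1 h. A difference between the cell lines stays open, because there is 1 HepG2 gamma-H2AX library and its read length differs from that of the K562 1 h libraries.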

How the results depend on the processing

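The settings without K562 24 h replicate 1 in comparisons that do not use it, or with a further change, were chosen after seeing the data. The H3K27me3 correlations over 10-kb windows divided by H2AX were not in the plan, which named 100-kb windows and no division. Their other settings, apart from the planned one, were chosen after seeing the data. Across the alternatives, 74 of the values that answer a comparison stayed on their side of the threshold or within their spread, 28 counts rose and 12 fell past 1.5 times or the threshold, in part with the number of windows tested, 16 values moved and 5 changed sign; none of the named windows changed direction, and of their values 851 kept their call, 183 lost it and 72 gained it. Counts of windows for 1 h against 24 h (13028), 1 h against H2AX (5107), HepG2 against H2AX (0) and K562 against HepG2 (0) became 0, 16939, 8557 and 13141 when only the compared groups were fitted. With 1-Mb windows, of which fewer exist, 1 h against 24 h gave 1363, 1 h against H2AX 0 and H3K27me3 against gamma-H2AX 2253, and with 10-kb windows 86217, 0 and 207451. As shares of the 276048 windows tested at 10 kb, 86217 is 31.2% (46.9% at 100 kb) and 207451 is 75.2% (83.4% at 100 kb), so these counts rose with the number of windows while the share called fell. Leaving out 1 replicate, alone or with 24 h replicate 1, gave 0 to 22660 for 1 h against 24 h, 0 to 24510 for 1 h against H2AX, 0 to 20709 for 24 h against H2AX and 0 to 20201 for K562 against HepG2. The zeros in 1 h against H2AX came with 24 h replicate 1 in the fit. Without that library, 1 h against H2AX gave 19666 and K562 against HepG2 12654; with median-of-ratios scaling as well they gave 20212 and 11686, and with the replicate block 20235 and 10595. Also without it, 1-Mb windows gave 1430 for 1 h against 24 h, 1882 for 1 h against H2AX and 927 for K562 against HepG2, and 10-kb windows 130386, 151501 and 78370. The replicate block on all libraries gave 12643, 6295 and 21918 for 1 h against 24 h, 1 h against H2AX and H3K27me3 against gamma-H2AX, and 0 for the other 3. The block ended the call of 8 of the 10 named windows with H3K27me3 below gamma-H2AX, of 1 named window higher at 1 h than at 24 h and of 1 higher than H2AX. Same-numbered libraries deviated together with correlations over 0.1 in 3 of 6 pairs of groups (0.430, 0.298 and 0.177) and from -0.163 to 0.0275 in the other 3; the labels name no shared batch, so the numbers were not taken as pairing, and pairing of some groups is not excluded. The overlap of 1 h peaks fell from 59.5% to 18.5% at 50% reciprocal overlap and to 0% for peaks with −log10 q of at least 5, of which 7 and 43 exist; the share of signal in such peaks has no value for lack of shared ones. Without the 0.1% of bins with most H2AX signal, K562 H2AX had 3.22% of its signal in 1 h peaks. Replicate rho moved to 0.888 (K562 1 h), 0.899 (K562 H2AX) and 0.764 (HepG2 H2AX) in 10-kb windows, and to 0.194 (24 h) and 0.962 (HepG2 H2AX) in 1-Mb windows. The rho of H3K27me3 with 1 h replicates 1 and 2 was -0.599 and -0.660 in 1-Mb windows; without division by H2AX it was -0.385 and -0.583 in 10-kb windows, -0.238 and -0.422 in 100-kb windows and, changing sign, 0.198 and 0.0213 in 1-Mb windows. With 24 h replicate 2 it was -0.314 in 100-kb and -0.623 in 1-Mb windows and, changing sign, 0.173, 0.226 and 0.295 without division in 10-kb, 100-kb and 1-Mb windows. The cause was not tested for these changes, apart from the window number and the shared spread. The planned count models, count scalings and count filters, gene bodies and promoter levels were not run.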

Other observations

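All tests of explanations in this part were chosen after the results were seen. Runs of K562 windows above H2AX at 1 h were shorter than runs below it. Counting 10-kb windows that differed from H2AX by more than 0.5 on the log2 scale in both replicates, 413 Mb lay above in 17187 runs with a median of 10 kb and a longest run of 440 kb. Below H2AX lay 863 Mb in 17702 runs with a median of 20 kb and a longest run of 1750 kb, and 52.6% of these windows belonged to runs of at least 100 kb, against 18.8% of those above.

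K562 24 h replicate 1 read 0 in all 933070 bins whose mean 1 h depth exceeded 1.642, the highest at which it held signal. Sampling at low depth would make zeros rarer where the 1 h depth was above its mean over bins, as in 24 h replicate 2 (0.321% against 5.06% below the mean), but in replicate 1 they rose from 4.76% to 96.4%. Loss of signal at 24 h is argued against by the library's own peak list, all 8 of whose peaks lie in bins where its track reads 0. Just below the depth of 1.642 only 0.374% of bins read 0, so the share stepped there and did not rise gradually, which is consistent with bins having been removed by a limit on the mean 1 h depth while the track was made. At which step this happened stays open.

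K562 gamma-H2AX at 1 h, relative to H2AX, was low where H3K27me3 was high. A read-length effect acting alike on the 60-bp libraries would make both deviate from H2AX in the same direction, and their rho over 100-kb windows was -0.771. This cannot decide the question, because that rho is the same relation at another window size. H3K27me3 also has a strong pattern of its own, which could set the sign whether or not such an effect is present. Read length therefore stays open. Copy number would be removed by dividing by H2AX and by looking within chromosomes, and the highest rho of any chromosome was -0.657. Cleavage of open chromatin, which CUT&RUN can give with any antibody, remains a candidate explanation: untreated K562 H2AX was also raised in the 1 h peaks, by 1.13- and 1.15-fold over the surrounding bins, though far less than the 1.87-fold at 1 h, and HepG2 H2AX by 1.11-fold. Gamma-H2AX in K562 24 h replicate 2 and in HepG2 was raised there by only 1.09- and 1.07-fold. H3K27me3 was at 0.166-fold, so not every antibody gave a rise. The H2AX rises are small and do not decide the question. A preference of break marking for chromatin without H3K27me3 also stays open, as gamma-H2AX in unirradiated cells was not analysed here.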
